A study of Mus musculus with 3 samples.

How the data were processed

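Single-cell RNA libraries of the thymus were analysed from 3 female mice of 4 weeks, 1 library per genotype (p53+/-, p53 AD/- and p53-/-). Groups were taken from the genotype labels. The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, which the authors made with Cell Ranger 4.0.0 per the file headers, on genome build GRCm38 per the submitters' processing notes. The deposited counts covered 32285 genes and 25077 barcodes called as cells. The gene annotation, the library chemistry and the use of strand in counting are not given in the sources used here. Gene positions were taken from GENCODE M21 on GRCm38, in which 32235 of the genes (99.85%) were found by identifier. UMIs collapse PCR copies, so counts stand for molecules, but RNA of burst cells is counted in all droplets and 2 cells in 1 droplet are counted as 1.

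Barcodes with fewer than 500 genes (443, 111 and 246 in p53+/-, p53 AD/- and p53-/-) or with 10% or more mitochondrial UMIs (559, 77 and 251) were left out. Scrublet was run on each library and called 1 of 25077 barcodes, so doublet calling has not worked and doublets remain. This left 91.8%, 97.8% and 96.5% of barcodes, with median UMIs of 3239, 2484 and 3062. Cells of the 3 libraries were clustered together without batch integration in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9): counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without receptor segment, mitochondrial and ribosomal genes, 30 principal components, 15 neighbours and Leiden resolution 1 (seed 1) were used. Clusters were named from markers of 17 cell classes. A name needed at least 3 markers detected in 5% of the cluster's cells, at least 1 of its own markers among the cluster's top 10 genes, and no more of another class there. The need for an own marker among the top 10 was set after a 13-cell cluster of histone genes had been named. It keeps out that cluster 13 (0.16%, 0% and 0% of cells) and cluster 11 (0.11%, 0.13% and 0.01%). Top genes were ranked on mean log-scaled values, which was chosen after 4 cells were seen to carry most haemoglobin UMIs of a cluster.

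UMIs were summed per library and class and given as CPM of all UMIs of the class. With 1 library per genotype no test was made and no p-value is given. Shares have exact Clopper-Pearson 95% intervals, CPM exact Poisson intervals and ratios exact conditional binomial intervals, all for counting error only. For ranking genes and for the ratios of ranked genes, counts under 3 UMIs were set to a floor of 3. For medians of ratios the floor was 1 UMI. The main class was the quiescent DP-like one, chosen with the rule for named genes: in each pair of libraries, the 10 genes with the highest and the 10 with the lowest log2 CPM ratio among those with at least 100 UMIs over the pair, leaving out mitochondrial, ribosomal protein, haemoglobin, receptor segment and unnamed genes. Trp53, and 3 members with at least 100 UMIs of the p53 target list and of each list outside the central 95%, were named too. Some genes that this rule selects are left out of the text. A gene over 20 times higher elsewhere in the same library, for either library of the pair, is given as possible free RNA. The plan compared whole classes for this, but the single clusters outside the main class were used instead, for list members as well. For 23 gene lists, the median log2 ratio of members with at least 30 UMIs was set against 10000 random lists of the same size, drawn from bins of 200 genes of like expression. The percentile describes these libraries. The lists, markers, rule and design were fixed before the data were examined. In all, 3 list genes were not found and 78 genes with a duplicated symbol were left out of lists and naming. Use of 35 T cell receptor beta variable (Trbv) genes and median ratios per chromosome were also computed.

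Alternatives were at least 1000 genes per cell, under 5% mitochondrial UMIs, called doublets kept, Leiden resolutions 0.5 and 2, 3000 variable genes, cycle genes left out of clustering, each library clustered alone, all filtered cells together, TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios factors, the mean over cells of CPM, and members with at least 100 UMIs or with no minimum. After the data were seen, the barcodes with the highest Scrublet scores were left out (631, 318 and 782 cells, 0.8% of a library per 1000 barcodes), and cells of the quiescent DP-like class were matched on their Malat1 share in bins of 0.5% (2011 cells per library), with 20 repeated draws for 5 of the lists. The procedures were tested on simulated data with 200 changed genes among 10750, 10798 and 11230 genes for p53 AD/- over p53-/-, p53 AD/- over p53+/- and p53-/- over p53+/-. In that order the 95% interval held the true ratio of 95.8%, 96.0% and 95.4% of unchanged genes, excluded 0 on the right side for 98.5%, 98.6% and 100.0% of genes changed 2.0-fold and for 87.1%, 81.2% and 88.7% of those changed 1.5-fold, and 5.25%, 4.00% and 3.25% of 400 unchanged lists lay outside the central 95%. The simulated counts were drawn independently per gene from a pooled profile of the pair, and the unchanged lists at random. The simulation therefore covers counting error only, and not lists of co-regulated genes or differences between libraries. Figures were drawn with matplotlib 3.10.9.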

Results

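The series measured single-cell RNA of the thymus of 4-week-old female mice with germline alterations of p53, the transcription factor encoded by Trp53 that responds to DNA damage. There were 3 libraries, 1 per genotype: p53+/-, p53 AD/- and p53-/-. The labels do not spell out the AD allele, and the series title speaks of p53 dimers. The design text names the first group as WT, whereas its sample label gives p53+/-, so this library is called p53+/- throughout. The question stated by the design text is how cell populations differ between genotypes, and the title adds a question about metabolism. The deposited values were unique molecular identifier (UMI) counts per gene and cell barcode. The p53+/- library held 8880 barcodes and 46498800 UMIs, the p53 AD/- library 6308 barcodes and 27638820 UMIs, and the p53-/- library 9889 barcodes and 54164425 UMIs. Median UMIs per barcode were 3109.5, 2455.5 and 2988 in that order. The strain labels name C57BL6, C57BL7 and C57BL8 beside BALB/C in the same order, and were read here as 1 mixed background, which is an assumption. After filtering, 8150, 6170 and 9543 cells remained. With 1 library per genotype there was no replicate, so no test between genotypes could be made and every comparison below is between libraries. All intervals are exact 95% intervals that cover counting error only.

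Thymocytes at the stage between T cell receptor beta and alpha selection were the largest class of each library. Clusters led by Rag1, which cuts receptor gene segments, and by Cd8b1, Cd4, Arpp21 and Themis were named quiescent DP-like (CD4-positive CD8-positive). They held 54.5% of the p53+/- cells (interval 53.5 to 55.6), 53.3% of the p53 AD/- cells (52.1 to 54.6) and 47.5% of the p53-/- cells (46.5 to 48.5). Cycling cells, led by Top2a, Nusap1, Mki67 and replication genes such as Mcm6 and Pcna, held 13.5% (12.8 to 14.3), 12.9% (12.11 to 13.8) and 18.0% (17.3 to 18.8). The cycling share was highest in the p53-/- library in each of the 9 other ways of filtering and clustering the cells. With the cycle genes left out of clustering the shares were 13.5%, 12.9% and 18.2%. Selected DP and early single-positive (SP)-like cells, led by Cd5, Tox, Itm2a and Cd2 and in cluster 5 also by the activation genes Nr4a1, Nfkb1, Rel and Cd69, held 20.8%, 22.4% and 20.04%. Mature SP-like cells, led by Ccr7, Klf2, H2-K1 and the interferon-induced Ifi27l2a, held 7.20% (6.65 to 7.79), 7.36% (6.72 to 8.04) and 8.65% (8.09 to 9.23). DN-like cells (CD4-negative CD8-negative), led by Il2ra, Hes1 and Notch1, held 1.14% (0.92 to 1.40), 0.86% (0.64 to 1.12) and 1.52% (1.28 to 1.79). Gamma-delta T-like cells numbered 8, 6 and 10, and stromal or endothelial-like cells 11, 9 and 15. The remaining 2.52%, 2.90% and 4.03% stayed unnamed. With at least 1000 genes per cell the quiescent share was 48.0% in p53 AD/- and 49.7% in p53-/-, the opposite order. That filter changes which cells are counted, since cells of this class had medians of 1064 genes in p53 AD/-, 1210.5 in p53-/- and 1325 in p53+/-.

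**Figure D1:**
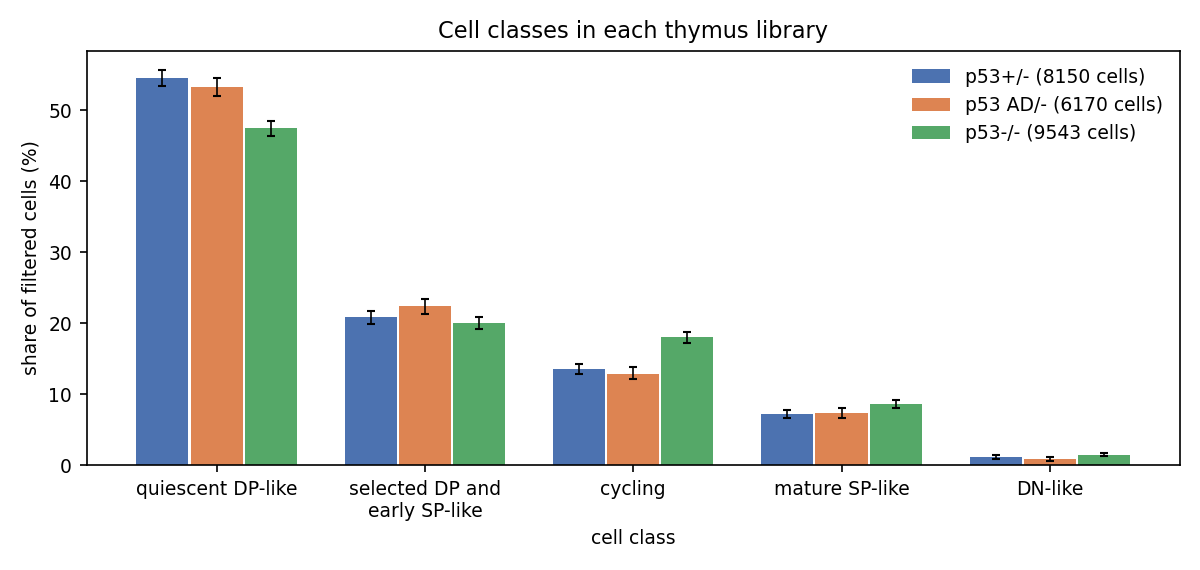
Share of filtered cells (percent, vertical axis starting at 0) in 5 cell classes (horizontal axis) for the p53+/-, p53 AD/- and p53-/- libraries, with bars for the share and error bars for the exact 95% binomial interval, which covers counting error only. The p53-/- library has the highest cycling share, 18.0%, against 13.5% and 12.9%, and the lowest quiescent DP-like share, 47.5%.

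Trp53 itself (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, GRCm38) was counted in all 3 libraries. In quiescent DP-like cells its level was 57.5 CPM (53.5 to 61.8, 744 UMIs) in p53+/-, 71.2 CPM (65.0 to 77.7, 499 UMIs) in p53 AD/- and 44.3 CPM (40.5 to 48.4, 498 UMIs) in p53-/-. Cycling cells had 84.7, 74.5 and 74.6 CPM, selected cells 130, 139 and 117 CPM, mature SP-like cells 95.8, 111 and 80.4 CPM, and DN-like cells 129, 165 and 139 CPM. The labels do not say which part of the gene the null allele lacks, and counted reads can lie outside it, so these levels check the genotype labels little. The transcript was present in the library labelled p53-/-.

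The quiescent DP-like class was the main setting for genes, with 12934305 UMIs in 4445 p53+/- cells, 7013066 UMIs in 3289 p53 AD/- cells and 11229067 UMIs in 4530 p53-/- cells. The cluster that held the largest part of it differed between the libraries. Cluster 9 held 46.2% of the class in p53-/-, 9.16% in p53+/- and 1.0% in p53 AD/-. Cluster 0 held 42.5% of it in p53 AD/- and 17.6% and 17.2% in p53+/- and p53-/-, and cluster 7 held 13.3% of it in p53 AD/-, 0.36% in p53+/- and 0.31% in p53-/-. Cluster 6 held 35.1% of it in p53 AD/-, 28.1% in p53+/- and 5.21% in p53-/-, and cluster 2 held 28.6% in p53+/-, 22.2% in p53-/- and 4.20% in p53 AD/-. A cluster mostly of 1 library can stand for that library and not for a cell type. The libraries also differed in RNA make-up. The nuclear RNA Malat1 had a median share of 6.12% of a cell's UMIs in p53+/-, 3.73% in p53 AD/- and 7.42% in p53-/-. Cells with less than 1% Malat1 numbered 31 (0.70%), 663 (20.2%) and 23 (0.51%). Median mitochondrial shares were 4.31%, 3.50% and 3.89%, and median UMIs per cell of the class 2710, 1962 and 2263. Haemoglobin and other erythroid marker UMIs stood at 470, 51.2 and 144 CPM and granulocyte marker UMIs at 36.7, 4.85 and 48.6 CPM in the same cells.

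**Figure D2:**
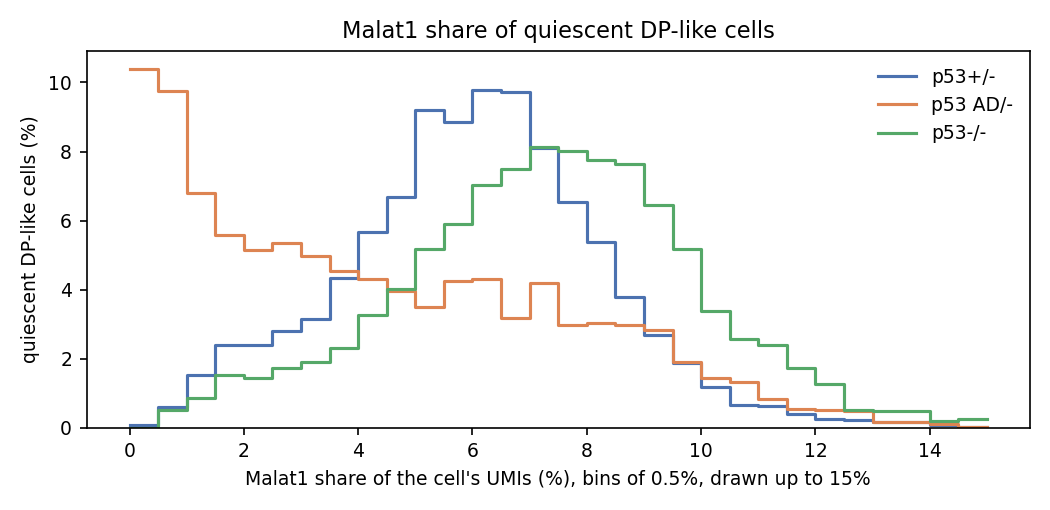
Share of quiescent DP-like cells (percent, vertical axis) by the Malat1 share of the cell's UMIs (percent, horizontal axis, bins of 0.5%, drawn up to 15%), one line per library. The p53 AD/- line is highest in the lowest bins, and 20.2% of its cells lie under 1%, against 0.70% in p53+/- and 0.51% in p53-/-.

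Between p53 AD/- and p53-/-, transcripts of glycolysis and of the nuclear-encoded respiratory chain were higher in p53 AD/- quiescent DP-like cells, and mitochondrially encoded, G2/M phase and glucocorticoid response transcripts were lower. Of 18 measured glycolysis genes, 13 were higher in p53 AD/-, with a median log2 ratio of 0.38, above 99.99% of 10000 random lists matched on expression. Eno1 (enolase) stood at 297 against 119 CPM, a log2 ratio of 1.32 (1.22 to 1.42), Pgam1 at 0.82 (0.61 to 1.03) and Ldhb, a lactate dehydrogenase subunit and a leading gene of clusters 0 and 7, at 0.78 (0.73 to 0.82), or 0.89 over all filtered cells. Of 71 oxidative phosphorylation genes 70 were higher, with a median of 0.36 and Ndufa3 at 0.88 (0.80 to 0.95) and Ndufv2 at 0.66. These genes have short transcripts (median 1005 against 3232 bases for all genes), and random lists matched on length as well had a median of 0.23. Of 13 mitochondrially encoded genes 12 were lower, with a median of -0.52, mt-Nd6 at -2.63 (-2.91 to -2.36), mt-Nd3 at -1.40 and mt-Atp8 at -1.40. Glucocorticoid response genes had a median of -0.62 and 13 of 14 were lower, among them Zfp36l2, an RNA-binding protein that promotes mRNA decay, at -2.10 (-2.25 to -1.95), Irs2 at -1.75 and Dusp1 at -1.59. G2/M genes had a median of -0.73, with 34 of 38 lower, such as Cdk1 at -1.98 (95 against 15 UMIs), Ccnb2 at -1.91 and Nusap1 at -1.32. The 16 markers of cycling cells, all of them members of the G2/M or S phase lists, stood at 172 CPM in p53 AD/- and 312 CPM in p53-/- in these cells. Cdk1, Ccnb2 and Nusap1 were 159, 304 and 212 times higher in another cluster of the p53 AD/- library, so they are possible free RNA here. The T cell lymphoma gene list had a median of -0.54, with 8 of 11 lower, including the receptor gene Notch1 at -1.21 (-1.46 to -0.97), Cdk6 at -0.83 and Ccnd1 at -0.80, the last possible free RNA too (25.15 times higher in another cluster of p53-/-). PPAR targets, which take part in fatty acid oxidation, had a median of 0.19 with 15 of 26 higher, including Ech1 at 0.95, Ucp2 at 0.61 and Acaa1a at 0.44. The median of the PPAR targets was -0.041 (percentile 73.2) in cells matched on their Malat1 share and 0.05 (percentile 91.9) over members with at least 100 UMIs, while scaling by TMM or median-of-ratios factors raised it to 0.32 and 0.33 (percentiles 99.7 and 99.6). Over all filtered cells the glucocorticoid and lymphoma medians were both -0.295, at percentiles 5.57 and 4.80, inside the central 95%, and the glycolysis, oxidative phosphorylation and G2/M medians were 0.23, 0.19 and -0.23, with Pgam1 at 0.45, Ndufv2 at 0.44, Cdk1 at -0.23, Ccnb2 at -0.095, Nusap1 at -0.28, Cdk6 at -1.26, Ccnd1 at -0.32 and Acaa1a at 0.27. Sums over all filtered cells, here and below, mix class shares with levels within a class. In cells matched on Malat1 share the oxidative phosphorylation median was 0.19, with Ndufv2 at 0.43, Ucp2 at 0.37 and Acaa1a at 0.19. The 7 lists named here were those outside the central 95% of random lists, of 23 lists. Chance would give 1.15 if the genes of a list varied independently, which co-regulated genes do not.

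The genes with the highest p53 AD/- over p53-/- ratios in these cells were led by Hist1h2ap, a histone H2A gene (ENSMUSG00000094777, chromosome 13, 21833026 to 21833507), at 2614 against 359 CPM, a log2 ratio of 2.86 (2.81 to 2.91). Gstp1, a glutathione S-transferase (ENSMUSG00000060803, chromosome 19, 4035407 to 4037985), stood at 2.63 (2.39 to 2.88) and Cdk5rap1, a tRNA-modifying enzyme (ENSMUSG00000027487, chromosome 2, 154335380 to 154373010), at 2.26 (1.86 to 2.67). Hist2h2aa1 (2.06), Bex1 (2.001), Hist1h2br (1.83), Bloc1s1 (1.80), Hist1h1e (1.68) and Hist2h3b (1.62) were also among the 10 highest. Histone genes and Gstp1 have near-identical copies between which counts can be split, so single members are uncertain. Slc15a2, a peptide transporter (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962), had 0 UMIs in p53 AD/- against 218 in p53-/- and 142 in p53+/-. With the floor of 3 UMIs its log2 ratio over p53-/- was at most -5.50. Nr4a1, an orphan nuclear receptor gene induced by T cell receptor signals (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795), stood at 4.85 against 76.2 CPM, a log2 ratio of -3.98 (-4.51 to -3.48). The other lower genes were B3gat2 (-4.15, 4 against 114 UMIs), S100a9 (-3.91), Insyn2b (-3.88), the noncoding RNA Snhg14 (-3.20), Snx18 (-3.14), Tsix (-3.02), the inhibitory receptor gene Ctla4 (-2.95) and Loxl2 (-2.80). Other nuclear RNAs, chosen after their values were seen, were lower in p53 AD/- too: Malat1 at -0.64, Neat1 at -0.71, Xist at -0.66 and Kcnq1ot1 at -0.98. Tsix overlaps Xist on the opposite strand, and whether the counting used strand is not given in the sources used here. S100a9 was 2309 times higher in another cluster of p53-/- and Nr4a1 57.8 times in another cluster of p53 AD/-, and so they are possible free RNA in this class. For Nr4a1 in p53-/- the value was 8.15 times. Leaving cell classes aside and summing all filtered cells, the ratio of Nr4a1 was -2.39 and that of Loxl2 -1.40. The same sum gave 2.76 for Hist1h2ap and -2.50 for Snx18, which are among the leading genes of clusters 6 and 9 of the class.

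Between p53 AD/- and p53+/-, glycolysis genes were again higher in p53 AD/-, with a median log2 ratio of 0.59 and 15 of 18 higher, and glucocorticoid response genes lower, with a median of -0.60 and 11 of 13 lower. Both pairs use the same p53 AD/- library, so they are not independent. Eno1 had a log2 ratio of 1.08 (0.99 to 1.17), Tpi1 0.98 (0.74 to 1.21) and Gapdh 0.97 (0.92 to 1.02), from 538 to 1053 CPM. Zfp36l2 stood at 60.5 against 408 CPM, a ratio of -2.76 (-2.90 to -2.61), Cxcr4, a chemokine receptor, at -1.16 and Tsc22d3, a classical glucocorticoid target, at -0.999 (-1.17 to -0.84). Tsc22d3 was about as low in p53-/-, with ratios of -0.08 (-0.27 to 0.10) for p53 AD/- over p53-/- and -0.92 (-1.05 to -0.78) for p53-/- over p53+/-. Mitochondrially encoded genes had a median of -0.64 with 12 of 13 lower, led by mt-Nd6 at -2.78, mt-Nd3 at -1.47 and mt-Nd5 at -1.06. Oxidative phosphorylation genes had a median of 0.27 with 66 of 71 higher, led by Atp5b at 0.67, Ndufv2 at 0.64 and Ndufv1 at 0.61, and random lists matched on length as well had a median of 0.19. TCA cycle genes had a median of 0.23 with 16 of 24 higher (Mdh1 0.76, Mdh2 0.64, Sdhb 0.50), and antioxidant genes a median of 0.23 with 17 of 23 higher (Gstp1 1.36, Gstm1 0.88, Gpx1 0.66), of which Gstm1 was 62.99 times higher in another cluster of p53+/- and is possible free RNA. In cells matched on Malat1 share the oxidative phosphorylation, TCA cycle and antioxidant medians were 0.15, 0.14 and 0.17, at percentiles 96.1, 92.4 and 94.5, inside the central 95%, with Gapdh at 0.63, Atp5b at 0.39, Mdh1 at 0.49 and Mdh2 at 0.39. Over all filtered cells the oxidative phosphorylation and TCA cycle medians were 0.16 and 0.14, at percentiles 97.3 and 96.6, also inside, and the ratio of Tpi1 was 0.51.

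Single genes higher in p53 AD/- than in p53+/- were Bex1 (ENSMUSG00000050071, chromosome X, 136213972 to 136215513), at 53.5 against 9.05 CPM with a log2 ratio of 2.56 (2.26 to 2.88), Lypd1 (2.21), the heat shock co-chaperone gene Hsph1 (1.87), Rab4a (1.43), Noc4l (1.41), Fam110b (1.40), Mzb1 (1.37), Macrod2 (1.36), Gstp1 (1.36) and P3h4 (1.27). Lower genes besides Zfp36l2 were Slc15a2 (at most -4.68), S100a9 (-3.47), Insyn2b (-2.64), Snhg14 (-2.47), S100a8 (-2.27), Tsix (-2.23), Scn4b (-2.07), Clspn (-2.06) and Tmem108 (-2.05). Malat1, Neat1, Xist and Kcnq1ot1 stood at -0.37, -0.70, -0.80 and -0.825 in this pair. S100a8, S100a9 and Clspn were 787, 2154 and 77.6 times higher in another cluster of p53 AD/-, and Mzb1 45.1 times in another cluster of p53+/-, which marks them as possible free RNA here. Over all filtered cells the ratios of S100a9, S100a8, Clspn, Mzb1, Hsph1 and Macrod2 were -0.38, -0.89, -0.45, 0.44, 1.204 and 0.87, and in cells matched on Malat1 share that of Fam110b was 0.885.

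Between p53-/- and p53+/-, cell cycle transcripts were higher in p53-/- quiescent DP-like cells. G2/M genes had a median log2 ratio of 0.45, with 34 of 39 higher, among them Ndc80 at 1.07 (0.70 to 1.46), Top2a at 0.998 (0.80 to 1.19) and Cdca3 at 0.84. The 16 markers of cycling cells stood at 312 CPM in p53-/- and 232 CPM in p53+/- in these cells, beside cycling shares of 18.0% and 13.5%. Whether cycling cells or their free RNA brought these UMIs was not tested. S phase genes had a median of 0.24 with 27 of 33 higher, among them Ccne2 at 1.31, Pola1 at 0.98 and Gins2 at 0.80, but 5 alternatives brought this median inside the central 95%, including cells matched on Malat1 share (0.18, percentile 90.5), and TMM and median-of-ratios factors lowered it to 0.14 and 0.15, still outside. Oxidative phosphorylation genes had a median of -0.10 with 58 of 71 lower (Ndufa3 -0.33, Uqcr11 -0.28, Ndufb3 -0.27). The oxidative phosphorylation median was -0.195 and -0.19 with TMM and median-of-ratios factors and -0.05 in cells matched on Malat1 share, each still below the central 95%. These 3 of 23 lists lay outside the central 95%. Higher single genes were Trim16 (2.79, 90 against 15 UMIs), Olfr1369-ps1 (2.15), Klf4 (2.14), Nr4a1 (2.05, 76.2 against 18.4 CPM), Nr4a3 (1.94), Snx18, a sorting nexin gene of membrane trafficking (ENSMUSG00000042364, chromosome 13, 113592179 to 113618564; 1.80, 1.68 to 1.93), Dusp5, a phosphatase of ERK kinases (ENSMUSG00000034765, chromosome 19, 53529109 to 53542431; 1.75, 1.66 to 1.84), Nr4a2 (1.68), Lyz2 (1.62) and Loxl2 (1.56). Klf4, Nr4a1, Nr4a3, Nr4a2, Lyz2 and Loxl2 were 95.3, 22.3, 74.9, 21.9, 379 and 31.4 times higher in another cluster of p53+/-, and Ndc80, Top2a, Cdca3, Ccne2 and Pola1 24.8, 82.6, 59.2, 46.8 and 27.2 times, so all are possible free RNA there. In p53-/- Nr4a1, Nr4a3 and Nr4a2 were 8.15, 23.1 and 7.91 times higher in another cluster. Lower single genes included Cdk5rap1 (-2.51, 6.15 against 35.02 CPM), Dynlt1c (-1.81) and 7 histone genes of chromosome 13: Hist1h3b (-2.40), Hist1h2ap (-2.23), Hist1h2br (-1.80), Hist1h2ad (-1.52), Hist1h2bb (-1.45), Hist1h3c (-1.40) and Hist1h3f (-1.39). Hist1h3b and Hist1h3c were 115 and 125 times higher in another cluster of p53-/- and Hist1h2bb 29.75 times in another cluster of p53+/-, and they are possible free RNA too. Snx18 and Dusp5 are among the 10 leading genes of cluster 9 and Hist1h2ap of cluster 6. Without any clustering, over all filtered cells, their p53-/- over p53+/- ratios were 1.35, 1.46 and -1.86, and those of Klf4, Nr4a1, Nr4a3, Nr4a2 and Loxl2 were 1.17, 1.28, 0.99, 0.75 and 0.998. The same sum gave -0.85, -0.585 and -0.83 for Hist1h2bb, Hist1h3c and Hist1h3f, and 0.41, 0.60 and 0.46 for Ndc80, Top2a and Cdca3. It gave 0.79, 0.49 and 0.29 for Ccne2, Pola1 and Gins2. The oxidative phosphorylation median was -0.02 in it, with Uqcr11 at -0.12 and Ndufb3 at -0.16. This sum mixes class shares with levels within a class. Cycling cells held 24078842 of its 53812231 UMIs in p53-/- and 17385718 of 45557301 in p53+/-.

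**Figure D3:**
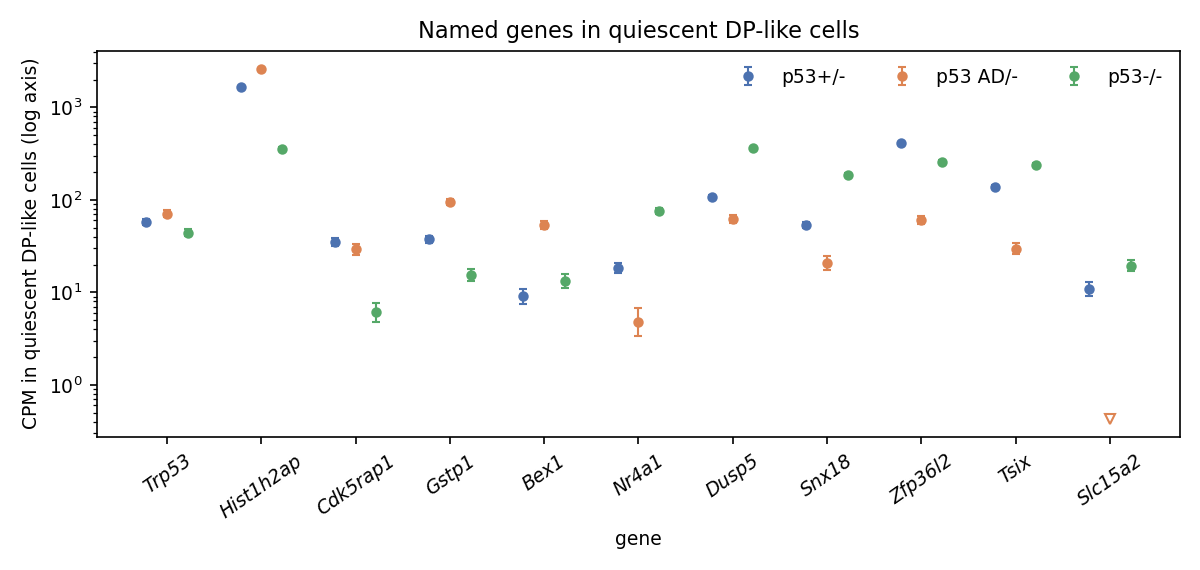
Level of 11 genes in quiescent DP-like cells (CPM, log axis) by library, with points for the summed UMIs and error bars for the exact 95% Poisson interval, which covers counting error only. The open triangle marks Slc15a2 in p53 AD/-, with 0 UMIs, drawn at the floor of 3 UMIs. Hist1h2ap and Cdk5rap1 are lowest in p53-/-, Nr4a1, Dusp5, Snx18 and Tsix are lowest in p53 AD/- and highest in p53-/-, and Trp53 lies between 44.3 and 71.2 CPM.

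Known p53 target genes did not stand apart in any pair in these cells. Their median log2 ratio was -0.20 for p53 AD/- over p53-/- (9 of 32 higher, percentile 38.0), -0.10 for p53 AD/- over p53+/- (13 of 31 higher, percentile 30.4) and 0.10 for p53-/- over p53+/- (20 of 33 higher, percentile 49.4). The median of all measured genes was -0.13, -0.045 and 0.09 in these pairs, so the p53 target medians lay close to it. Scaling by TMM factors moved the median of all genes to -0.003, -0.01 and -0.003 and that of the p53 targets to -0.067 for p53 AD/- over p53-/- and 0.003 for p53-/- over p53+/-, and median-of-ratios factors gave -0.049, -0.051 and 0.006 for the p53 targets in the 3 pairs. The apoptosome gene Apaf1 was lower in p53 AD/- than in p53-/- (-1.02, -1.38 to -0.67) and in p53+/- (-0.92), as were Zmat3 (-0.89 and -0.60) and Trp53inp1 (-0.61 and -0.53). Ckap2 (0.51, -0.07 to 1.11), Tob1 (0.45) and the nucleotide excision repair gene Xpc (0.37) had the highest p53-/- over p53+/- ratios, and Ckap2 was 40.2 times higher in another cluster of p53+/-, possible free RNA. Over all filtered cells the ratios of Zmat3 were -0.21 and -0.25 and that of Xpc 0.16, and in cells matched on Malat1 share Ckap2 stood at 0.79 and Tob1 at 0.72. Cdkn1a, which encodes the cell cycle inhibitor p21, had 15, 6 and 11 UMIs in p53+/-, p53 AD/- and p53-/-, too few to tell the libraries apart. Mdm2, whose product degrades p53, stood at 80.6, 81.4 and 93.4 CPM. Cdkn1a and Mdm2 were named after their values were seen. In cells matched on Malat1 share the p53-/- over p53+/- median of the p53 targets was -0.125, and that of all genes was 0.085. In 20 repeated draws of such cells the p53 target median ran from -0.10 to 0.12, with a middle value of 0.014. Its percentile among random lists ran from 0.1 to 67.8, and it lay below the central 95% in 1 draw.

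**Figure D4:**
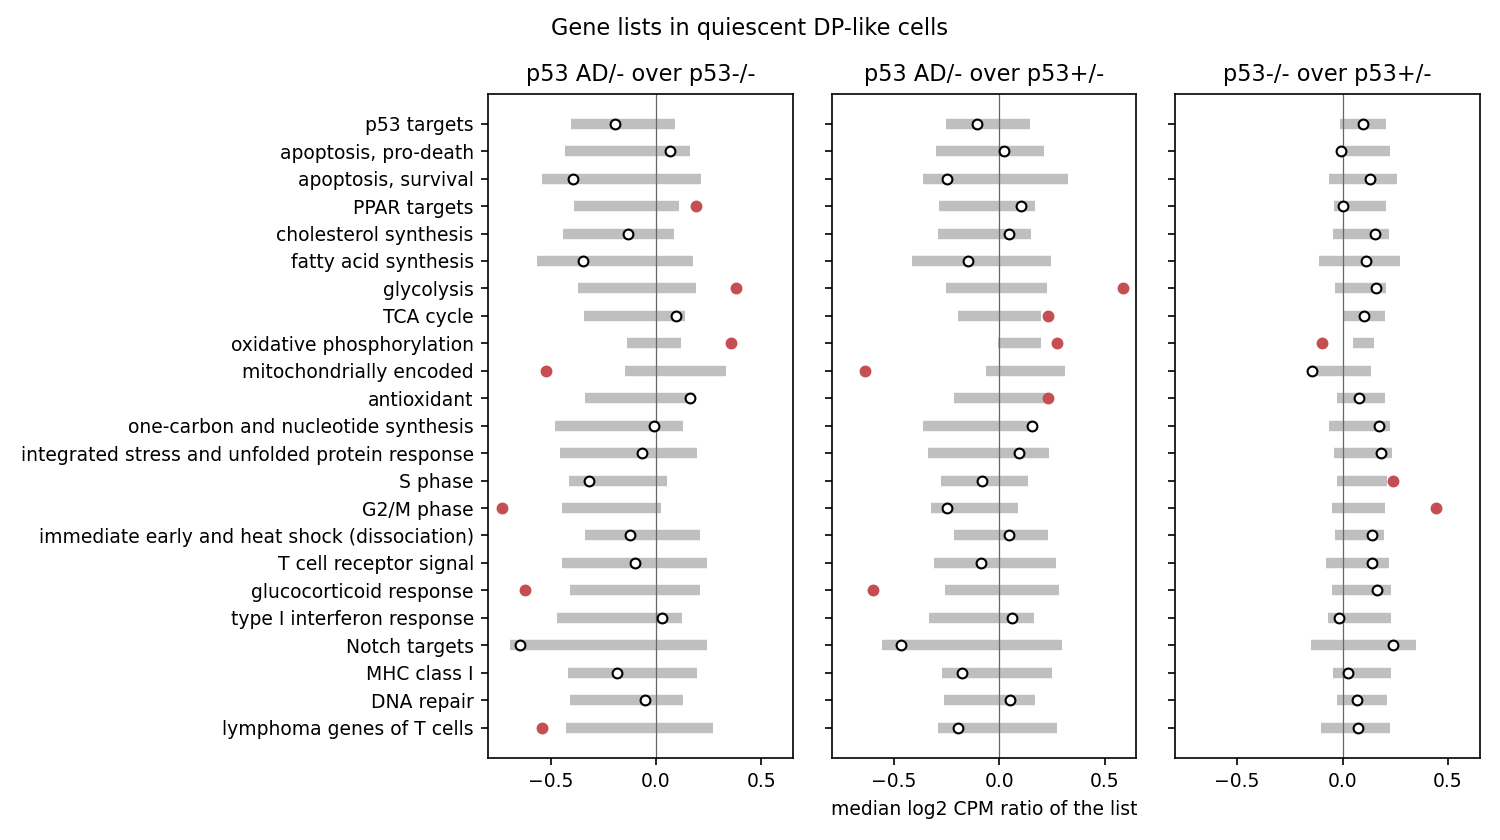
Median log2 CPM ratio (horizontal axis) of each of 23 gene lists (vertical axis) in quiescent DP-like cells for the 3 pairs of libraries. Grey bars span the central 95% of 10000 random lists matched on expression, filled points lie outside it and open points inside. Glycolysis stands highest in both pairs with p53 AD/-, at 0.38 and 0.59, and G2/M phase highest for p53-/- over p53+/-, at 0.45.

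Of the 23 lists, 12 besides the p53 targets lay inside the central 95% in all 3 pairs in quiescent DP-like cells. In the order p53 AD/- over p53-/-, p53 AD/- over p53+/- and p53-/- over p53+/-, the medians were 0.07, 0.02 and -0.008 for pro-death genes of apoptosis, -0.39, -0.25 and 0.13 for its survival genes, and -0.13, 0.04 and 0.15 for cholesterol synthesis. They were -0.345, -0.15 and 0.11 for fatty acid synthesis, -0.008, 0.155 and 0.17 for one-carbon and nucleotide synthesis, and -0.06, 0.10 and 0.18 for the integrated stress and unfolded protein response. Immediate early and heat shock genes had medians of -0.12, 0.045 and 0.14, T cell receptor signal genes -0.10, -0.09 and 0.14, and type I interferon response genes 0.03, 0.06 and -0.02. Notch targets had -0.64, -0.465 and 0.24, MHC class I genes -0.185, -0.18 and 0.03, and DNA repair genes -0.05, 0.05 and 0.07.

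Other cell classes gave the same direction for most of these genes. Of the 10 genes highest and the 10 lowest in each pair, 10 and 10 had the same sign in the cycling, selected and mature SP-like classes for p53 AD/- over p53-/-, 8 and 9 for p53 AD/- over p53+/-, and 10 and 10 for p53-/- over p53+/-, although some of these values rest on few UMIs. Dusp5, for example, had p53-/- over p53+/- ratios of 1.72, 1.46 and 1.40 in the 3 classes. For Lypd1 and Scn4b in mature SP-like cells, with 3 UMIs over the pair, the floor and the class totals alone set the sign. The classes come from the same libraries, so their agreement is not independent. Lists outside the central 95% numbered 7, 9 and 7 in cycling cells, 7, 8 and 5 in selected cells and 11, 12 and 5 in mature SP-like cells, in the order p53 AD/- over p53-/-, p53 AD/- over p53+/- and p53-/- over p53+/-. In cycling cells Cdkn1a was higher in p53 AD/-, at 11.1 CPM (9.14 to 13.3) against 3.11 (2.33 to 4.05) in p53+/- and 4.78 (3.94 to 5.73) in p53-/-, while the p53 target medians were -0.20, -0.17 and 0.03, at percentiles 70.7, 44.3 and 6.88. Summed over all filtered cells, Cdkn1a had a p53 AD/- over p53-/- log2 ratio of -0.031 (-0.227 to 0.163). In that sum its ratios over p53+/- were 1.095 for p53 AD/- and 1.125 for p53-/-. The sum mixes class shares with levels within a class, so it does not speak for cycling cells. DN-like cells, 1.52% of p53-/- and 0.86% of p53 AD/- cells, held 175 of 652 and 53 of 326 Cdkn1a UMIs.

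No large clone or chromosome change was visible. Among T cell receptor beta variable genes Trbv2 had the largest share of UMIs in each library, 18.4% (17.5 to 19.3) in p53+/-, 16.4% (15.3 to 17.6) in p53 AD/- and 20.1% (19.2 to 21.1) in p53-/-, followed by Trbv13-2 at 10.03%, 9.03% and 8.64%. In mature SP-like cells Trbv2 held 20.3%, 22.7% and 22.1%. Chromosome medians of the log2 ratio in quiescent DP-like cells lay between -0.08 and 0.08 of the median of all genes in the 3 pairs, the widest being -0.08 for chromosome 1 in p53 AD/- over p53+/-. A clone or change carried by a small part of the cells would not be seen this way.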

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

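Of the tests in this part, the one on the share of the selected class and those on transcript length and on neighbouring genes of chromosome 13 were set before their results were seen, and all others only after. Genotype and library cannot be told apart with 1 library each, and a strain difference outside chromosome 13 was not tested, with labels that name C57BL6, C57BL7 and C57BL8 beside BALB/C and were read as 1 mixed background, so both stay open for every pattern here.

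In the p53 AD/- library, glycolysis and nuclear-encoded respiratory chain transcripts were higher and glucocorticoid response transcripts lower, and 20.2% of its quiescent DP-like cells had little Malat1. A loss of nuclear RNA from cells could shift such lists. In cells matched on Malat1 share 4 of 4 glycolysis and glucocorticoid medians stayed outside the central 95% of random lists. They did so in each of 20 repeated draws from the same cells, which argues against it as the whole cause for these lists. For the pairs with p53-/- and p53+/-, the middle glycolysis medians of the draws were 0.29 and 0.40, against 0.38 and 0.585 without matching. Such a loss may thus account for part of the glycolysis difference, but matching alone cannot show this. Malat1 share also differed between clusters of the class within p53+/-, at 4.37% in cluster 6 and 6.74% in cluster 2. Matching can therefore change which kinds of cells are compared, and this too could lower the medians. The glucocorticoid medians were -0.63 and -0.47, against -0.62 and -0.60 without matching. For oxidative phosphorylation 1 of 2 medians stayed outside. In the pair with p53-/- the median lay above the central 95% in 20 of 20 draws, which argues against a loss of nuclear RNA as the whole cause there. The middle median of these draws was 0.17 against 0.36 without matching, so such a loss may account for part of it, with the same limit. In the pair with p53+/- the median lay above in 11 of 20 draws (middle 0.15 against 0.27), so there it stays open. Malat1 share and transcript length were not matched together. Against lists matched on expression and length, 6 of 6 medians lay outside the central 95%. Glycolysis and glucocorticoid genes had median lengths (3227.5, and 3313 and 3096 bases) near those of all genes (3232 and 3219). A length trend would shift these lists little, so matching on length adds little for them. For the short oxidative phosphorylation genes, the medians outside argue against a length trend as the whole cause. Lists matched on length had medians of 0.23 and 0.19 there against 0.36 and 0.27, so length may account for part of it. A difference made by the genotype stays open as an untested biological explanation.

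In the p53-/- library, Hist1h2ap, Cdk5rap1, Gstp1 and several histone genes had low counts, and Hist1h3b, Hist1h3c and Hist1h2bb are possible free RNA. Fewer S phase transcripts could lower histone counts, but the S phase median was not below the central 95%: it was 0.24 in quiescent DP-like cells, where Ccne2 and Pola1 are possible free RNA and 5 alternatives brought the median inside, and 0.051 (percentile 29.0) in cycling cells, where Hist1h2ap was low too (-2.05), and counts moved between copies are argued against for Hist1h2ap and Gstp1, since 2 of 2 family sums kept most of the log2 ratio (-1.67 and -1.06). The test of copies was split by gene family after its first result was seen. For Dynlt1c the family sum was -0.475, between the values named for either answer, and this stays open. A linked strain difference around the Hist1 genes stays open too, for these genes only: the median absolute log2 ratio of 15 neighbouring genes (0.235) lay at percentile 94.5 of random runs of genes. It could not cover Cdk5rap1 and Gstp1, which lie on other chromosomes.

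Nr4a1, Nr4a2 and Nr4a3, induced by T cell receptor signals, were higher in quiescent DP-like cells of the p53-/- library. Cells or free RNA of the selected class could bring them. At the mean level of that class the share needed for Nr4a1 is 24.9%. This predicts a median log2 ratio of 1.19 for 8 other markers, and 0.022 was observed, which argues against free RNA of that mean make-up. The test cannot decide for cells, since clustering on expression takes cells high in these markers out of the class. In p53-/- Nr4a1 was 8.15 times higher in cluster 5, against 3.28 times in the whole selected class. A source in cluster 5 would need a smaller share and was not tested. A response to cell dissociation stays open: the immediate early and heat shock list lay at percentile 81.3 in quiescent DP-like cells but above the central 95% of random lists in 2 of 4 classes, cycling (99.3) and mature SP-like (99.1), and inside it in selected cells (95.9), while Nr4a1 was higher in all 3 of these (1.66, 0.74 and 1.06). This test was widened from 1 class to 4 after its first result was seen. An effect of the genotype stays open and untested.

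Some lists moved in opposite directions in different cell classes, and the differences between classes were not tested. G2/M genes had p53 AD/- over p53-/- medians of 0.56 in mature SP-like cells, -0.73 in quiescent DP-like and -0.72 in selected cells. Their p53 AD/- over p53+/- medians were 0.16 in cycling, 0.91 in mature SP-like and -0.34 in selected cells. T cell receptor signal genes had p53-/- over p53+/- medians of 0.36 in cycling and -0.10 in selected cells.

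Some clusters outside the named classes held more than 3 cells of a library, and their shares, which enter no comparison between libraries, are given as values only. In the order p53+/-, p53 AD/- and p53-/-, cluster 8 (Cd74, S100a8, Krt8) held 0.33%, 0.49% and 0.62% of cells, cluster 19 (Ms4a4b, Nkg7, Top2a) 0.77%, 0.83% and 1.01%, cluster 20 (Icos, Maf, Zbtb16, Izumo1r) 0.36%, 0.34% and 0.81%, and cluster 22 (Cd74, H2-Aa, Ctss, Tyrobp) 0.79%, 1.12% and 1.59%. Cluster 11, led by the interferon-induced Isg15 and Ifit1, held 0.11% in p53+/- and 0.13% in p53 AD/-, and cluster 13, led by histone genes, 0.16% in p53+/- and 0 cells in the other libraries.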

How the results depend on the processing

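The cells matched on Malat1 share and the removal of the highest Scrublet scores were chosen only after the results were seen. No paired analysis was possible because each genotype has 1 library and no test was made. Of the class shares under alternatives 61 stayed within their counting interval and 69 moved beyond it, and values below are in the order p53+/-, p53 AD/- and p53-/- unless a library is named. The cause was not tested, except that the filters on genes and mitochondrial UMIs change which cells are counted, and that keeping the called doublet adds only 1 barcode. With at least 1000 genes per cell, quiescent DP-like shares were 59.0%, 48.0% and 49.7%, selected 18.1%, 23.8% and 17.0%, cycling 16.7% in p53 AD/- and 20.3% in p53-/-, mature SP-like 5.86% in p53+/- and 7.64% in p53-/-, and Trp53 was 49.8 CPM in p53-/-. Under 5% mitochondrial UMIs, quiescent shares were 50.3% in p53+/- and 45.2% in p53-/-, cycling 15.5% and 19.5% in the same libraries, selected 18.5%, 20.6% and 16.0%, and 5 lists lay outside the central 95% for p53-/- over p53+/-. With the called doublet kept, quiescent shares were 57.1%, 56.6% and 48.7%, and selected 19.5% in p53+/- and 20.1% in p53 AD/-. This setting adds 1 barcode, in p53 AD/-, so these moves come from instability of the clustering and not from doublets. The counting intervals therefore do not bound the shares. At resolution 0.5, quiescent shares were 56.3% in p53+/- and 55.4% in p53 AD/-, selected 19.8% and 21.1% in the same libraries, and mature SP-like 7.98%, 8.14% and 9.39%. At resolution 2, quiescent shares were 53.1%, 54.6% and 46.4%, cycling 12.15%, 11.8% and 17.1%, selected 17.5%, 17.0% and 17.8%, and mature SP-like 6.33%, 6.45% and 7.69%. With 3000 variable genes, the quiescent share was 52.8% in p53+/-, selected 23.4% in p53+/- and 21.7% in p53-/-, and mature SP-like 6.27% and 7.63% in these. With cycle genes left out, quiescent shares were 53.2%, 51.2% and 48.9%, and selected 23.2% in p53+/- and 25.5% in p53 AD/-. Without the highest Scrublet scores, quiescent shares were 53.02% in p53+/- and 55.8% in p53 AD/-, selected 23.5%, 21.02% and 21.9%, and mature SP-like 6.44%, 6.52% and 7.36%. With each library clustered alone, quiescent shares were 49.8%, 51.2% and 42.0%, selected 14.6%, 15.5% and 18.3%, mature SP-like 6.63%, 6.16% and 6.12%, and cycling 11.4% in p53+/-. No cluster was named DN-like under 5% mitochondrial UMIs, nor in p53+/- and p53 AD/- clustered alone. Over all filtered cells Trp53 was 86.1, 90.8 and 74.9 CPM and 9 lists lay outside for p53-/- over p53+/-. In cells matched on Malat1 share the p53 target medians were -0.069 for p53 AD/- over p53-/- and -0.125 for p53-/- over p53+/-, the PPAR target median for p53 AD/- over p53-/- reversed to -0.041, and 5 lists lay outside for p53-/- over p53+/-. The p53 target medians for p53 AD/- over p53-/- and p53-/- over p53+/- were -0.067 and 0.003 with TMM factors and -0.049 and 0.006 with median-of-ratios factors. In mature SP-like cells Trbv2 held 20.3%, 22.7% and 22.1% of Trbv UMIs. Of the values of list medians under alternatives, 243 differed from the main value by less than 1 standard deviation of the random-list medians. Another 41 moved further and 1 reversed sign. Reversal was counted only for lists outside the central 95% in the main setting, so the p53 target median of -0.125 counts as moved. Of the values of single genes 1328 stayed within their counting interval, 167 moved and 0 reversed. Depth limits genes of few UMIs, such as Cdkn1a in quiescent cells.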

Other observations

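The repeated draws of cells matched on Malat1 share were chosen only after the results were seen. Cholesterol synthesis transcripts were higher in the p53 AD/- library in cycling, selected and mature SP-like cells. Against p53-/- the list medians were 0.215, 0.20 and 0.485, and against p53+/- 0.24, 0.15 and 0.33, all outside the central 95% of random lists, while in quiescent DP-like cells both were inside. In cycling cells Fdps, which makes farnesyl diphosphate, had a p53 AD/- over p53-/- log2 ratio of 0.72 (0.625 to 0.81, 153 against 92.7 CPM), Fdft1, squalene synthase, 0.71 (0.465 to 0.95) and Msmo1 0.68 (0.43 to 0.93). Against p53+/- they stood at 0.88, 1.02 and 0.80. Fdps, Fdft1, Msmo1 and Cdkn1a were named here after their values were seen. The differences between classes were not tested.

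Cells under 1% Malat1 made up 57.8% of the cycling, 16.9% of the selected, 41.9% of the mature SP-like and 75.5% of the DN-like cells in p53 AD/-, against 57.5%, 0.82%, 5.28% and 32.3% in p53+/- and 46.3%, 0.21%, 3.64% and 28.3% in p53-/-. The values of these classes were not matched on Malat1 share.

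In mature SP-like cells, one-carbon and nucleotide synthesis genes were higher in p53 AD/- than in p53-/- (median 0.27, 20 of 22 higher) and p53+/- (0.33, 18 of 22 higher), as were S phase genes (0.26 and 0.44) and G2/M genes (0.56 and 0.91). Survival genes of apoptosis were lower, with medians of -0.515 and -0.39 and 0 of 11 members higher in both pairs. In DN-like cells Cdkn1a stood at 60.2 CPM (48.2 to 74.3) in p53+/-, 71.7 (53.7 to 93.8) in p53 AD/- and 96.9 (83.1 to 112) in p53-/-.

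In 20 repeated draws of cells matched on Malat1 share, the glycolysis median lay above the central 95% of random lists in 20 draws for both p53 AD/- pairs and in 0 for p53-/- over p53+/-. The glucocorticoid median lay below it in 20 draws for both p53 AD/- pairs and in 0 for p53-/- over p53+/-. The oxidative phosphorylation median for p53-/- over p53+/- lay below it in 20 draws.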
